A study of Mus musculus with 6 samples.

How the data were processed

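RNA was measured in 6 libraries of mouse pancreatic islets, 3 WT and 3 KO. Per the labels' protocols, total RNA was extracted with a column kit and 500 ng went into a strand-specific library preparation. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.10b and featureCounts 2.0.3, with the mm10 genome build. The gene annotation, the parameters and the strand setting of the counting step are not given in the sources used here. If the strand was not used, reads of a gene and of its antisense partner could not be separated. The authors deposited a table of raw counts per gene, with 40840 rows named by symbol and 1 column per library, and no normalized values were used. Column names give the genotype and a number from 1 to 3. The titles number the KO samples from 4 to 6, so KO columns were used as libraries of the KO group with no link to a title, and the numbers are column numbers. Of the rows, 30614 matched a symbol of GENCODE M21 on GRCm38, the reference used for positions, transcript length and GC content. Of the 13 symbols of the mitochondrially encoded list, 0 were in the table and that list was not analysed here.

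From the counts, genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 16240 genes holding 99.8% to 99.9% of each library. TMM factors ranged from 0.986 to 1.02. KO was tested against WT with glmQLFit (robust) and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. The common biological coefficient of variation was 0.0796, and the median SE of a log2 fold change was 0.0826 for genes above 1 log2 CPM. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01) where at least 4 members were tested, adjusted over 37 lists, with camera's estimated correlation and fry as alternatives. Shares and ratios per library were compared by an exact two-sided permutation test. DESeq2 1.42.0 and limma-voom were alternative tools, run in R 4.3.3. DESeq2 gave 6076 genes an adjusted p, and genes without one stayed out of its counts.

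The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule always takes Igf2r, Igf2, Ins1, Ins2, Gcg, Sst and M6pr. It adds called genes whose groups do not overlap, with mean log2 CPM of at least 1 and no placeholder symbol, 10 by fold in each direction and 10 by p. Where fewer than 10 genes were called in a direction, the 10 with the smallest p that meet the same conditions on overlap, level and symbol are named as values. For each list it takes up to 4 called members, or else the 2 with the highest CPM. Some genes and a list that these rules take are not reported here. Other genes, such as Hexa, Iapp, Cyc1, Maf and Tff2, are named from within a list by their p or value, which was chosen after their values were seen.

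The tests were also run on simulated data drawn from the real means, library sizes and dispersions for KO against WT, with 200 of 16240 genes changed. edgeR called 10% of genes changed by 1.2-fold, 70% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 14 unchanged genes. In simulated sets of 40 genes, camera with the preset correlation called 10 of 10 sets raised by 0.1 log2 and 0 of 30 unshifted ones. Of the raised sets, fry called 90% and camera with an estimated correlation called 0%. Genes were drawn independently there, while the correlation estimated in the real lists reached 0.927 (acinar). The 0 of 30 therefore does not give camera's rate of false calls in correlated lists. A trend correction on GC content and transcript length left a slope of -3.99e-06 per percent GC of an added 0.0298. All pairs of replicates differed by more than sampling noise, with a chi-square of at least 4.52 per degree of freedom. Each library counted as 1 replicate, and this comparison cannot show whether the libraries are independent samples.

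The alternatives were 3 other scalings, 2 other tools, 2 other filters, no robust estimation, leaving out abundant or acinar genes, an acinar covariate, each library left out in turn, and 2 other thresholds. A comparison with WT library 3 alone and a block by column number were added after the data were seen.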

Results

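The data were gene-level read counts from RNA sequencing of mouse pancreatic islets, the hormone-secreting micro-organs of the pancreas. The title of the series names the role of IGF2R in beta cells as its subject. Igf2r encodes the cation-independent mannose 6-phosphate receptor, which carries lysosomal enzymes from the Golgi to endosomes and takes up insulin-like growth factor 2. There were 3 wild-type (WT) and 3 knockout (KO) libraries on a C57BL/6J background. Total counts ranged from 16943764 to 18757633 in WT and from 16689319 to 18956235 in KO libraries. The libraries are numbered here as their columns are. The labels do not say that the 3 libraries of a genotype came from separate animals. Each p-value of a gene, a share or a ratio is therefore judged against the spread between these libraries, which may be technical. The p-values of camera compare the members of a list with the other genes. The labels state neither sex nor the way the gene was removed. Every library carried transcripts of the Y-linked gene Ddx3y, from 1029 counts in KO library 2 to 1640 in WT library 1, while Xist, the transcript of the inactive X chromosome, had 4 to 19 counts.

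The first question was whether the targeted transcript was lower in the islets labelled KO. Igf2r fell in all 3 KO libraries, from 113 ± 16.5 CPM (counts scaled by library size; mean ± SD, n = 3) in WT to 48.6 ± 0.59 CPM (SD, n = 3) in KO. The log2 fold change was -1.21 (SE 0.0946), a change of -56.8%, and the adjusted p of edgeR's quasi-likelihood test was 0.00261. Single libraries held 1790, 2145 and 2097 Igf2r counts in WT and 928, 841 and 823 counts in KO. The gene lies on chromosome 17, from 12682406 to 12769664 on the minus strand of GRCm38, and its annotated exons cover 9308 bases. The labels do not say which exons were removed, and the counts are sums over the whole gene. The antisense transcript Airn overlaps the gene on the plus strand with 0 exonic bases in common, and its log2 fold change was -0.25 (edgeR adjusted p 0.491). The Igf2r call was lost without KO library 1 (edgeR adjusted p 0.13) or KO library 2 (0.192), with log2 fold changes of -1.22 and -1.20. Over all settings its adjusted p ranged from 1.62e-82 to 0.284, the highest with the acinar level described later as a covariate (log2 fold change -1.25).

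**Figure D1:**
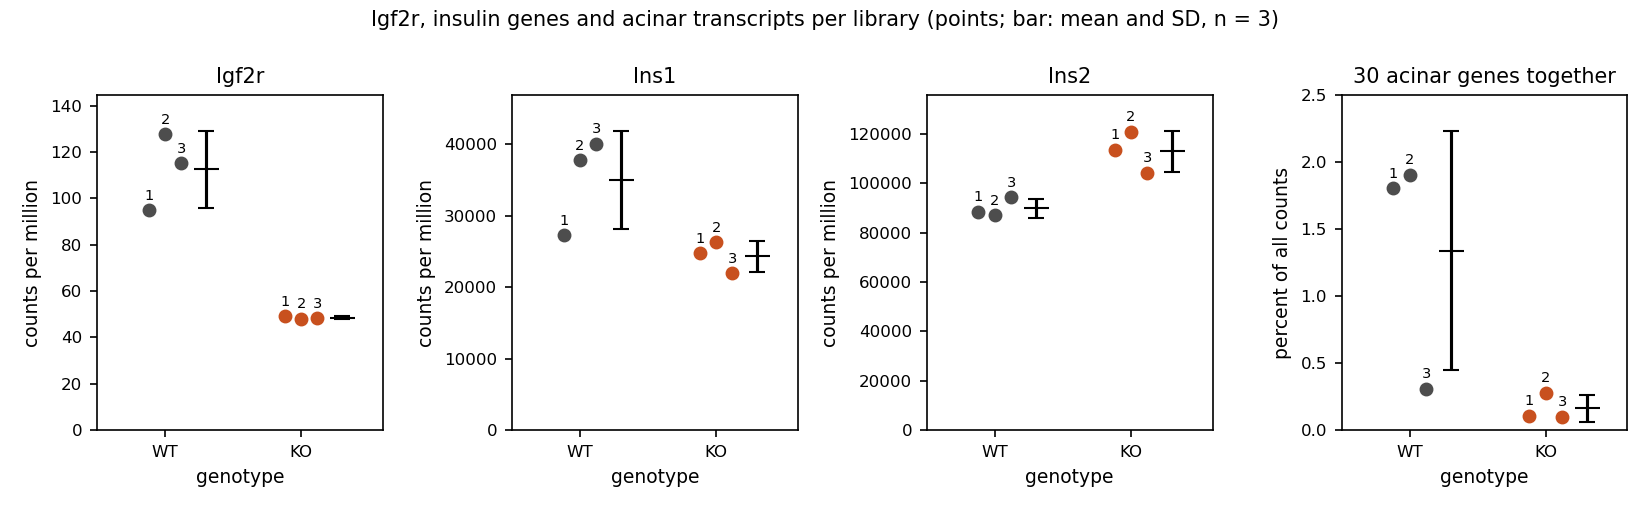
Level of Igf2r, Ins1 and Ins2 in CPM (y axis, from 0) and share of all counts held by 30 acinar genes in percent, for each WT (grey) and KO (orange) library, numbered by column; the bar beside each group is the mean and SD of 3 libraries. Igf2r averaged 113 CPM in WT and 48.6 CPM in KO, and the acinar share of WT library 3 (0.310%) lay near that of KO library 2 (0.279%).

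Across the islet transcriptome, the comparison of KO with WT asked which other genes differed. Besides Igf2r, the only gene past the threshold was Vwde, which encodes a von Willebrand factor D and EGF domain protein. Vwde fell from 38.7 ± 4.84 CPM to 26.7 ± 1.11 CPM (SD, n = 3), a log2 fold change of -0.53 (SE 0.0838, edgeR adjusted p 0.0302), and it lies on chromosome 6, from 13156299 to 13224965. The Vwde call was lost without WT library 1 (edgeR adjusted p 0.141), WT library 2 (0.162), KO library 1 (0.13) or KO library 2 (0.686), with log2 fold changes of -0.57 to -0.47, and without robust estimation (0.071). It was also lost against WT library 3 alone (0.999) and with the acinar covariate (adjusted p 1), with log2 fold changes of -0.31 and -0.28. Of 16240 genes tested, edgeR called 0 higher and 2 lower in KO. At an unadjusted p under 0.05 there were 843 higher and 942 lower genes, 1785 in all, where 812 would be expected by chance. A mixed split of the same libraries, WT libraries 1 and 2 with KO library 1 against the rest, had 1741. The excess alone therefore does not point to genotype. The 3 KO and 3 WT values did not overlap for 15.7% of genes, against 10% by chance. DESeq2, which used its own filter, called 62 genes (22 higher, 40 lower), of which 18 belonged to the acinar list described next. Its lower genes outside that list included Klk1 (log2 fold change -3.29), Dmbt1 (-2.99), Pla2g1b (-2.88), Amy2a1 (-3.45) and 2210010C04Rik (-3.05). Like the acinar genes, these were highest in WT libraries 1 and 2. limma-voom called 3 genes (1 higher, 2 lower). The count of called genes also depended on single libraries. Without WT library 3 edgeR called 114 genes, without KO library 3 it called 24, without WT library 1 it called 1, and without KO library 1 or KO library 2 it called 0. Against WT library 3 alone, an alternative chosen after seeing the data that assumes this library varies like the KO libraries, edgeR called 3 genes, Ppy higher and Igf2r and Ins1 lower.

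**Figure D2:**
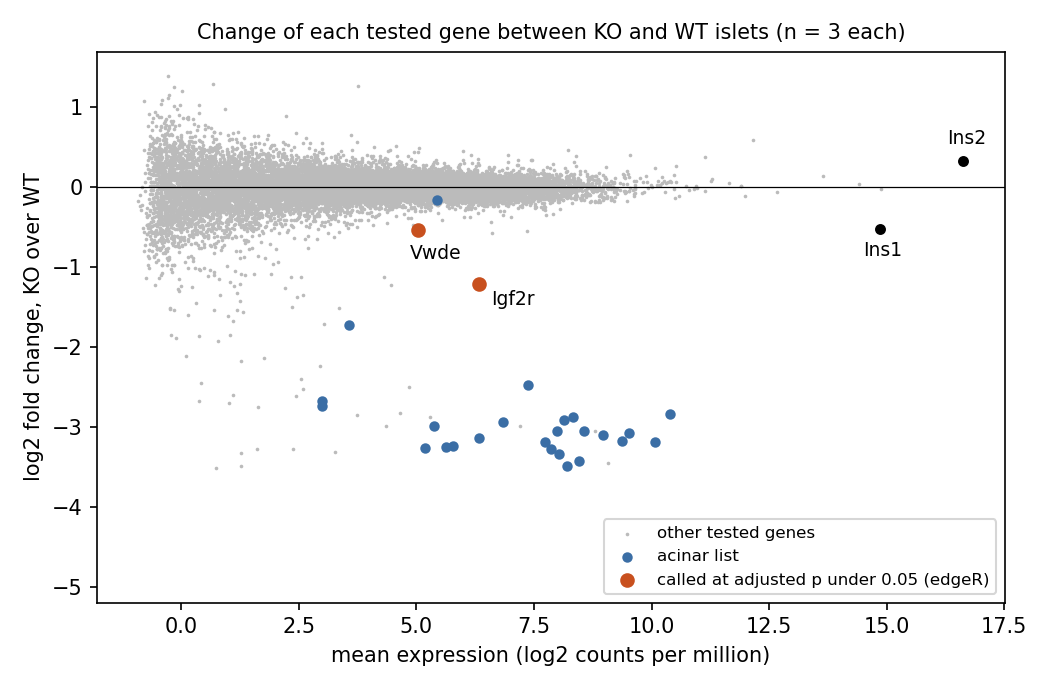
log2 fold change of KO over WT (y axis) against mean expression in log2 CPM (x axis) for 16240 tested genes. Orange points are the 2 genes called by edgeR, blue points are the 25 tested genes of the acinar list, and grey points are all other genes, with Ins1 and Ins2 in black.

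Below those genes, 10 per direction were taken by smallest p among genes that did not pass. They also had to have groups that do not overlap, a mean log2 CPM of at least 1 and no placeholder symbol. At an adjusted p under 0.1 edgeR called 3 genes lower, so a gene with a smaller p that missed these conditions is not among them. The higher values in KO included Npr3, a natriuretic peptide receptor (log2 fold change 0.89, from 3.18 to 5.91 CPM), Zdhhc22 (0.65), and Rasd1, a small GTPase (0.44). Insm1, a transcription factor of endocrine cells, stood at 154 ± 12.9 CPM in WT and 196 ± 15.3 CPM in KO (SD, n = 3; log2 fold change 0.34). Mfsd13a (0.35), Rps4l (0.34), Ky (0.32), Lgi1 (0.29), Pitpnm3 (0.28) and Rnasek (0.25) completed this group. On the lower side, those named were Ces1d (log2 fold change -1.32), Dlk1, an imprinted Notch-like ligand (-0.87), Nphs1 (-0.61), Dcdc5 (-0.56), Gpr179 (-0.47) and Msln (-0.45). The sodium channel gene Scn9a (-0.33), the glutamate receptor subunit gene Grin2c (-0.29) and Itpr3, an inositol trisphosphate receptor (-0.25), were also on that side. The choice required that the 3 KO libraries lie on one side of the 3 WT libraries, so this held for all 20 genes. Their edgeR adjusted p ranged from 0.192 to 0.211. Without a low-count filter edgeR called all 20, and DESeq2 called 9, among them Insm1 (adjusted p 0.0033) and Itpr3 (0.00597). Without WT library 3 edgeR called 13 of them and without KO library 3 it called 7, with Insm1 called in both (edgeR adjusted p 0.0252 and 0.0214). When WT library 1, WT library 2, KO library 1 or KO library 2 was left out, edgeR called 0 of the 20. limma-voom, and edgeR with each of the 3 other scalings, also called 0 of them.

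Transcripts of acinar cells, the digestive-enzyme cells that surround islets, were lower in KO. All 25 tested members of the 30-gene acinar list had negative log2 fold changes, with a median of -3.08, and the list was called by camera (adjusted p 1.06e-18, and adjusted p 0.769 with an estimated correlation). The chymotrypsinogen gene Ctrb1 stood at 2359 ± 1566 CPM in WT and 329 ± 161 CPM in KO (SD, n = 3), and the lipase gene Pnlip at 1940 ± 1301 and 212 ± 157 CPM. None of the 25 was called by edgeR over all genes tested, and 23 were called adjusted over the list alone. The acinar genes took 1.80% and 1.91% of counts in WT libraries 1 and 2 and 0.310% in WT library 3, against 0.108%, 0.279% and 0.1002% in the KO libraries. The 95% Clopper-Pearson interval of each share, which covers counting error only, was at most 0.013 percentage points wide. The means were 1.34 ± 0.894% and 0.162 ± 0.101% (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest p that 3 against 3 allows. The first principal component, 39.6% of the variance, set WT libraries 1 and 2 (-25.8 and -22.4) apart from WT library 3 (5.23) and the KO libraries (10.2 to 17.1). Of the duct list, 8 of 9 tested genes had negative values, among them the trefoil factor gene Tff2 (-2.82) and Muc1 (-1.13). That list was not called (camera adjusted p 0.0524), but it was in 5 of 18 alternative settings, among them without WT library 3 (0.00568). The REG family had 3 tested members, too few for the list test, with Reg3d at -3.28 and Reg2 at -2.24 (neither called).

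The hormone genes were compared next, since beta cells are the named subject. The 2 mouse insulin genes had values in opposite directions. Ins2 stood at 89946 ± 3828 CPM in WT and 112900 ± 8302 CPM in KO (SD, n = 3), a log2 fold change of 0.33 (SE 0.0555). Ins1 stood at 34999 ± 6835 CPM in WT and 24309 ± 2176 CPM in KO (SD, n = 3), a log2 fold change of -0.53 (SE 0.182). Neither passed edgeR over all genes tested (adjusted p 0.211 for Ins2 and 0.439 for Ins1). DESeq2 called Ins2 (adjusted p 1.27e-05) and did not call Ins1 (adjusted p 0.145), and limma-voom also called Ins2 (adjusted p 0.0431). edgeR did not call Ins2 without WT library 1 (adjusted p 0.371), WT library 2 (0.49), KO library 1 (0.227) or KO library 2 (0.686). Without WT library 3 or KO library 3, edgeR called Ins2 (adjusted p 0.00879 and 1.65e-05), and against WT library 3 alone it called Ins1 (adjusted p 0.00154) and not Ins2 (0.999). The ratio of Ins1 to Ins2 counts was 0.308, 0.433 and 0.425 in the WT libraries and 0.217, 0.217 and 0.211 in the KO libraries, with means of 0.389 ± 0.0701 and 0.215 ± 0.00389 (SD, n = 3; exact two-sided permutation p 0.1, the smallest the design allows). The 2 genes are close paralogs, and the sources used here do not say how reads that match both were counted, so the split between them is uncertain. Insulin transcripts together held 12.5 ± 0.921% of counts in WT and 13.7 ± 0.816% in KO (SD, n = 3; exact two-sided permutation p 0.2). Of the other hormones, glucagon (Gcg, log2 fold change -0.03) and somatostatin (Sst, 0.01) differed by less than the spread between libraries. Pancreatic polypeptide (Ppy) had a log2 fold change of 0.60 (SE 0.233, edgeR adjusted p 0.472) and peptide YY (Pyy) of 0.37 (SE 0.146, edgeR adjusted p 0.463). edgeR called both without WT library 2 (adjusted p 3.24e-08 and 0.00284), the WT library nearest to KO for both genes. Ppy stood at 4821 CPM there, against 3017 and 3004 CPM in WT libraries 1 and 3 and 5159 to 5831 CPM in KO. Pyy stood at 2349 CPM there, against 1691 and 1844 CPM in WT libraries 1 and 3 and 2383 to 2753 CPM in KO.

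Of 24 beta cell identity genes, 15 had higher and 9 lower values in KO, and the list was not called (camera adjusted p 0.228). Adjusted over the list alone, edgeR called 4 of them, all higher in KO, against 0 over all genes tested. They were Ins2, the amyloid peptide gene Iapp (log2 fold change 0.14, from 12172 to 13453 CPM), and the transcription factor genes Nkx6-1 (0.22, from 155 to 181 CPM) and Foxa2 (0.16, from 129 to 144 CPM). The list of genes normally silenced in beta cells fell, with 17 of 19 members lower and a median log2 fold change of -0.12 (camera adjusted p 0.00729, and adjusted p 0.769 with an estimated correlation). Its members with the smallest p were Itih5 (-0.46), Maf (-0.80) and Slc16a1 (-0.56), which encodes a lactate and pyruvate transporter, and 0 were called by edgeR, over all genes tested or over the list alone. Maf was at 4.66 CPM in WT library 1, against 2.08 and 1.76 CPM in WT libraries 2 and 3 and 1.33 to 1.88 CPM in KO, and Slc16a1 at 1.58 CPM in WT. The call was lost without KO library 1 (camera adjusted p 0.285), against WT library 3 alone (0.0767) and with the acinar covariate (0.503). Of the 14 stellate and fibroblast markers, 8 were also lower, with a median of -0.14 (list not called, camera adjusted p 0.306). Genes for exocytosis and excitability (9 of 24 higher) and for secretory granules (11 of 19 higher) were not called, with Abcc8, the sulfonylurea receptor gene, at 1966 ± 107 and 1986 ± 36.3 CPM (SD, n = 3) in WT and KO.

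Lysosomal genes, whose enzymes are the cargo of the mannose 6-phosphate receptors, rose slightly as a group. Of 49 hydrolase and other cargo genes, 39 were higher in KO, with a median log2 fold change of 0.07 (camera adjusted p 0.00217, and adjusted p 0.769 with an estimated correlation). The members with the smallest p were Hexa, a hexosaminidase subunit gene (log2 fold change 0.17, from 213 ± 5.89 to 239 ± 8.56 CPM, SD, n = 3), Galns (0.17) and the cathepsin gene Ctss (0.15). Of 32 lysosomal membrane and proton pump genes, 23 were higher, with a median of 0.04 (camera adjusted p 0.0207, and 0.769 with an estimated correlation). In that list the proton pump subunit gene Atp6v0b had a log2 fold change of 0.24 and the tetraspanin gene Cd63 of 0.17. No single member of either list was called by edgeR, over all genes tested or over the list alone. The calls were made in libraries that differed in acinar share, and against WT library 3 alone neither list was called (camera adjusted p 0.642 and 0.746). The hydrolase call was lost without WT library 2 (camera adjusted p 0.0652), and the membrane call without WT library 2 (0.199) or KO library 1 (0.154).

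The sorting machinery that works with the receptor was not called as a list. Of 29 sorting, trans-Golgi and retromer genes, 20 were higher and 9 lower in KO, with a median log2 fold change of 0.01 (camera adjusted p 0.565). M6pr, the cation-dependent mannose 6-phosphate receptor gene, stood at 110 ± 5.18 CPM in WT and 107 ± 2.04 CPM in KO (SD, n = 3), a log2 fold change of -0.04 (SE 0.0523), and Sort1 at 316 and 317 CPM. Igf2, the growth factor gene, was at 14.2 ± 0.642 and 14.9 ± 0.951 CPM (SD, n = 3), a log2 fold change of 0.07 (SE 0.0951). Insulin-like growth factor and insulin signalling genes (8 of 25 higher) and autophagy genes (15 of 26 higher) were not called, with camera adjusted p of 0.566 and 0.705. In the 12 tested genes near Igf2r, 5 were higher and 7 lower, and the list was not called (camera adjusted p 0.705).

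Ribosomal protein and respiratory chain genes also rose slightly. Of 36 cytosolic ribosomal protein genes, 34 were higher in KO, with a median log2 fold change of 0.08 (camera adjusted p 0.00217, and adjusted p 0.769 with an estimated correlation). The groups did not overlap for 2 of the 36, and the correlation estimated between these genes was 0.673, against the preset 0.01. Mitochondrial ribosomal and transfer RNAs also took a larger share of counts in every KO library, 0.061 ± 0.00205% against 0.0529 ± 0.00271% in WT (SD, n = 3; exact two-sided permutation p 0.1, the smallest the design allows). Of these, mt-Rnr2 had a log2 fold change of 0.25 and was called by DESeq2 (adjusted p 0.00862) and not by edgeR (0.211). Rpl4 stood at 885 ± 29.8 and 929 ± 30.8 CPM (SD, n = 3). Of 26 nuclear-encoded oxidative phosphorylation genes, 21 were higher, with a median of 0.06 (camera adjusted p 0.0276, and 0.769 with an estimated correlation). The cytochrome c1 gene Cyc1 (log2 fold change 0.25, from 36.6 to 43.5 CPM) was the only member called by edgeR adjusted over the list alone. All 5 tested erythroid genes were higher, with a median of 0.36 (camera adjusted p 0.0276, and 0.769 with an estimated correlation), at low levels such as 1.29 and 2.06 CPM for Hba-a1. Against WT library 3 alone none of these 3 lists was called (camera adjusted p 0.746, 0.746 and 0.967). The ribosomal call was lost without WT library 1 (0.134), KO library 2 (0.0606) or KO library 3 (0.095), and the respiratory chain call without WT library 1 (0.134), WT library 2 (0.0652), KO library 1 (0.0922) or KO library 3 (0.117). The erythroid call was lost without WT library 1 (0.101), WT library 2 (0.153), KO library 1 (0.0922) or KO library 2 (0.0865).

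**Figure D3:**
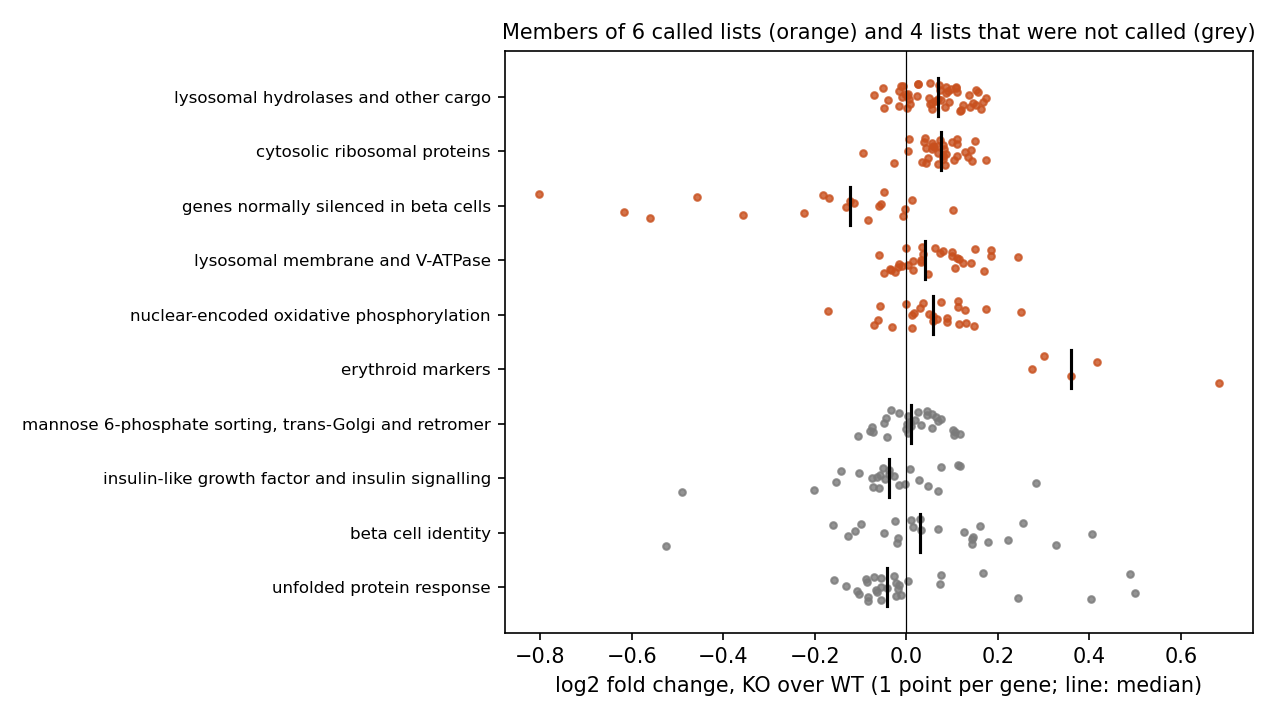
log2 fold change of KO over WT (x axis) for the members of 10 gene lists, 1 point per gene, with the median as a black line. Orange lists were called by camera and grey lists were not; the acinar list is off this scale, with a median of -3.08.

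In all, 37 of the 41 lists had enough tested members, and camera called 5 higher and 2 lower in KO. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.769. With the acinar level as a covariate camera called 0 of these 7 lists, and it called the alpha cell (adjusted p 0.01045) and cell cycle (0.0393) lists lower. That level is the mean log2 CPM of the acinar list, so the acinar call was lost by construction. It also ran with genotype (8.33, 8.48 and 5.92 in WT, 4.48, 5.81 and 4.35 in KO). The other losses can thus not be assigned to acinar RNA or to lost power. The set test fry called 1 list, the lactogen and growth hormone response (adjusted p 0.0495, 12 of 15 genes lower). In calcium handling, Itpr3 (-0.25) and Itpr1 (-0.25), 2 inositol trisphosphate receptor genes, were called adjusted over the list alone, and the list was called by fry's test for changes in either direction (adjusted p 0.0116). Among 21 tested imprinted genes, Dlk1 (-0.87) and Zdbf2 (-0.24) were called adjusted over the list alone, and of 27 cell cycle genes Bub1b (-1.21, from 3.16 to 1.37 CPM) was. Lists for the unfolded protein response, cholesterol and fatty acid synthesis, glycolysis, p53 targets, inflammation, interferon, stress, TGF-beta and progenitor genes were not called. The same held for alpha, delta, PP and epsilon, endothelial, stellate, macrophage and Schwann cell markers, where Kdr, an endothelial receptor gene, stood at 318 and 331 CPM. Camera called the alpha cell list lower without WT library 1 (adjusted p 0.00418) and against WT library 3 alone (0.0179), the PP and epsilon list higher without WT library 2 (0.00208), and the stellate list lower without KO library 3 (0.0406). Of 18 alternative settings, camera called the PP and epsilon list in 2 and the glycolysis list in 1 (lowest adjusted p 0.0463). Of the adipocyte list 1 gene was tested, Fabp4, with a log2 fold change of -0.28. Adjusted over the list alone, edgeR called C1qb in the macrophage list (0.33), and Cd74 (0.22) and Cd79a (-0.29) among 3 tested lymphocyte markers.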

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

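The comparison with WT library 3 alone and the block by column number were chosen after seeing the data. The 2 genes called by edgeR became 62 with DESeq2 (22 higher, 40 lower), where the filter differed along with the tool (26710 genes entered and 6076 received an adjusted p), and 272 without a low-count filter (108 higher, 164 lower). limma-voom called 1 gene higher, Ins2. Without robust estimation, and with a fold change of at least 1.5, 1 gene was called, lower in both settings. With the acinar level as a covariate 0 genes were called, 0 of them lower, and the Igf2r log2 fold change of -1.25 had an adjusted p of 0.284 in edgeR. Leaving out 1 library at a time gave 0 to 114 genes, 0 to 21 higher and 0 to 93 lower, and Igf2r log2 fold changes from -1.32 to -1.11. The KO numbers in these settings are column numbers. Against WT library 3 alone 1 gene was called higher. A replicate block by column number gave 30 genes (3 higher, 27 lower), and the columns share only a number: deviations of same-numbered libraries from their group means correlated at 0.0731, 0.097 and 0.0971, none over 0.1, although every library correlated best with its own number, a hint from the data and not from the design.

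Camera's 5 higher lists became 0 with the acinar covariate, against WT library 3 alone, with an estimated correlation and with fry, and 2 to 5 when 1 library was left out. With limma-voom 7 lists were higher. With the replicate block 4 lists were higher, the erythroid list being lost. The 2 lower lists became 1 when the acinar list was left out, by construction, 0 with an estimated correlation, and 1 to 4 when 1 library was left out. They became 3 with limma-voom, with library size only and with either other filter. On simulated sets camera with an estimated correlation called 0% of raised sets, so its 0 calls do not show that the lists stayed level. The test fry gave 1 lower list, the lactogen and growth hormone response, and neither of the 2. The cause of the other changes was not tested. Across all settings 0 named genes or lists reversed direction with a call. Among named genes, 70 results under an alternative gained a call, 10 lost one (Vwde and Igf2r) and 1853 stayed on their side of the threshold. Among lists 14 gained, 43 lost and 682 stayed. At the real depth, dispersion and number of libraries, none of which was varied, edgeR called 10% of genes changed by 1.2-fold in simulated data and 70% at 1.5-fold.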

Other observations

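The tests of explanations for the acinar and insulin patterns, and the one of exocrine RNA for the gene lists, were chosen only after the result was seen (GC content, scaling and the splits were fixed before). WT library 1 held transcripts that the other libraries nearly lacked. In it 77 genes reached at least 1 CPM and more than 8 times every other library, against 0 in WT libraries 2 and 3 and KO library 1, 8 in KO library 2 and 3 in KO library 3. They included the apolipoprotein genes Apoa4 at 270 CPM (highest other library 4.37), Apoa1 at 115 (6.59) and Apob at 67.0 (2.58), the immunoglobulin gene Ighm at 99.1 (4.96), the keratin gene Krt20 at 25.8 (0.959), the lactase gene Lct at 16.1 (0.539) and the mucin gene Muc2 at 15.1 (0.719). Of 30 genes of small intestinal epithelium, listed after these genes were seen, 13 met that rule in WT library 1 and 0 in any other library, and of 12 hepatocyte genes 0 did. KO library 3 was the highest other library for all those named except Ighm, and it held Alpi at 3.54 CPM and Fabp1 at 2.34 CPM, which had 0 counts in the other 4 libraries outside WT library 1. Of the 30 genes, 5 were at 1 CPM or more in all 6 libraries, and the 30 together stood at 1116 CPM in WT library 1 and 395 to 452 CPM in the others.

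Acinar transcripts were lower in KO, and exocrine tissue carried over into single preparations is a candidate explanation. The acinar profile added in WT library 1 over WT library 3 matched that added in KO library 2 over KO library 1, where genotype is constant, with a Pearson r of 0.983 across 24 genes, which are not independent replicates. A change that scaled all acinar genes alike would give the same r. Genotype stays open: the 3 WT and 3 KO libraries did not overlap for 72% of 25 genes, between the bounds set for and against it, and the acinar share of WT library 3 (0.310%) lay next to that of KO library 2 (0.279%). The 25 genes are not independent either (estimated correlation 0.927). Tissue carried over could give the same 72%, so this value cannot separate genotype from that source.

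Ins1 had a lower and Ins2 a higher mean in KO, neither past edgeR's threshold over all genes. A different share of beta cells alone would move both alike. The values argue against it as the only source: the genes moved in opposite directions, by -2.89 and 5.91 times their SE. Those directions are the pattern itself and not a separate test, and a different share together with one of the sources below is not excluded. Reads moved between the paralogs cannot be told apart from a change, since the summed CPM of KO was 1.10 times that of WT and the libraries overlapped, while Ins2 gained 22952 CPM and Ins1 lost 10690. A missing Ins1 allele in KO, as in mouse lines that carry Cre at Ins1, may also be the source: the KO to WT quotient of the Ins1 to Ins2 ratio was 0.554, and 0.487 to 0.707 over single pairs of libraries, but the labels name no driver and such an allele would coincide with genotype, so it cannot be told apart. Genotype itself stays open and untested.

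The lysosomal, ribosomal and respiratory chain lists rose slightly, with a median log2 fold change of 0.07 over 143 genes. Scaling cannot be told apart by the test run, which kept at least 0.978 of the median, because the other scalings moved the median of all genes by at most 0.00661. Exocrine RNA in the WT libraries is a candidate for part of the rise, not tested apart from other differences between these libraries. The median against WT library 3 alone was 0.305 of that against WT libraries 1 and 2 (bootstrap interval over genes 0.179 to 0.482), which rests on 1 library. This contrast is not specific to exocrine RNA, since WT library 1 also held the other transcripts described above. The lists were also chosen for their rise in these same libraries. The bootstrap intervals in this paragraph take genes as independent. A trend on GC content or transcript length cannot be told apart, because 0.466 of the median was left after its correction (0.317 to 0.614). Genotype stays open and untested.

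Splits of the 6 libraries into 3 and 3 make 10, too few for a share under 0.05. The real split called 2 genes, and the highest other called 12, with WT library 1 and KO libraries 1 and 2 on one side, several times the real count, as a structure of the samples can give. At an unadjusted p under 0.05 that split had 789 genes, fewer than the 812 that chance gives, and the real split 1785. The split of WT libraries 1 and 2 with KO library 1 had 1741, so a mixed split came close to the real count. Including the real split, 2 of the 10 called as many genes. The real split called 7 lists and the highest other 7, in 2 of 10 splits, and that other split set WT libraries 1 and 2 with KO library 2, whose acinar share was the highest of the KO libraries.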
